A study of Oryza sativa with 12 samples.

How the data were processed

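The 12 leaf libraries of rice at the booting stage, 3 for each combination of cultivar (Kongyu131, Dongnong422) and treatment (control, 17 °C), were used. Per the labels' protocols, total RNA was extracted with Trizol from leaves frozen in liquid nitrogen, ribosomal RNA was removed, and strand-specific libraries were made with a NEBNext Ultra Directional kit. Per the submitters' processing notes, TopHat2 2.0.9 and Cufflinks 2.1.1 were used. The notes do not give their order or settings, and the genome build, the annotation and the way transcripts were classed as lncRNA are not given in the sources used here. The authors deposited a table per library with a transcript identifier, a locus identifier, a class (lincRNA or antisense lncRNA) and an FPKM value, which is relative to transcript length and to the number of mapped fragments. The 12 tables list the same 1485 transcripts of 1039 loci, of which 828 loci have 1 transcript and 211 have more, up to 15. Of the identifiers, 0 matched the supplied table of rice gene names, and the tables give 0 symbols, so no host gene, position or gene list could be tied to a transcript, and the gene lists that had been fixed for cold regulators, photosynthesis and other functions were not tested.

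FPKM values are not counts, and no count model was applied. Ratios of low values of single-transcript loci between libraries showed no common step that would give whole reads (the most frequent ratio was shared by at most 5.5%), so the depth behind each value is unknown and no counting interval is given. Cufflinks divides the fragments of a locus among its transcripts, so values of transcripts in loci with several transcripts depend on that division. Values are also shares of a library total, so a change in a few abundant RNAs shifts the others, and 98.45% to 99.64% of the listed FPKM of a library lay in its 10 highest lncRNAs. An exact 0 can be a failed estimate as well as a lack of reads. Whether the strand was used in assigning reads is not given in the sources used here, so antisense values may include reads of the opposite gene.

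Values were used as deposited, without further scaling, as log2(FPKM + 0.1), after removal of 44 transcripts with a mean under 0.1 FPKM over the 12 libraries, which left 1441 (828 lincRNAs and 613 antisense lncRNAs). Fold changes are on this scale, which understates changes of low transcripts. A linear model with 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, so that the groups share an estimate of the spread for each transcript. The contrasts were cold against control in each cultivar, the average of these effects, their difference (Dongnong422 minus Kongyu131), and Dongnong422 against Kongyu131 in each treatment. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within a contrast. Overlaps of calls were compared with the product of the list lengths over the transcripts tested, by one-sided Fisher's exact tests. The classes were compared by two-sided Fisher's exact tests and by limma's camera (preset correlation 0.01, and estimated) and fry. No other column of the tables was used.

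Before the data were examined, the contrasts, the test, the filters and the rule for named transcripts were fixed. Since the identifiers carry no names, that rule names in each contrast the 2 transcripts with the largest rise and the 2 with the largest fall among those that were called, reached a mean of 1 FPKM in the higher group and had no overlap between the groups. The last condition was dropped for the difference of cold effects. Others are named where a count was small, and the text says so. The alternatives fixed at the same time were pseudocounts of 1 and 0.01 FPKM, no filter or a mean of at least 1 FPKM, median-ratio scaling, quantile normalization, no variance trend, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. Sums over the transcripts of a locus, the overlap from separate fits and the class comparisons on the highest transcript of each locus and within bins of expression, the scalings tried with fry, and the removal of the average cold effect before treatment was reassigned to test the difference of cold effects, were added after the data were seen.

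The procedure was tested on 20 simulated data sets with the means and spreads of the 1441 lncRNAs and with 50 changes planted at each of 4 sizes in cold Kongyu131 libraries. For cold against control in Kongyu131, it recovered 24.4%, 60.4%, 78.8% and 81.1% of changes of 1, 2, 3 and 4 on the log2 scale, and 4.77% of its calls were false. For the difference of cold effects it recovered 7.1%, 38.6%, 61% and 67.8%, and 5% of its calls were false, so smaller differences between cultivars would mostly be missed. The simulated noise was normal and independent between lncRNAs, with a common mean and spread over the groups. It held no scale differences between libraries and no library that stands apart. These shares therefore test the procedure under its own assumptions only. The real libraries had median-ratio scale factors from 0.964 to 1.36. Libraries of the same group were checked for duplicates, and none shared values above 0 (0% equal).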

Results

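Long non-coding RNAs (lncRNAs) were profiled by strand-specific RNA sequencing of rice (Oryza sativa) leaves at the booting stage, when the panicle is still enclosed in the flag leaf sheath. The design crossed 2 cultivars, Kongyu131 and Dongnong422, with 2 treatments, control and cold. It held 4 groups of 3 libraries each, 12 in all, and addressed which lncRNAs respond to cold at this stage. The cold treatment was 17 °C for 13 days in an incubator with 16 h of light and 8 h of darkness. That protocol is attached to the labels of all 12 libraries, controls included, so the temperature and place of the controls are not stated separately, and an effect of temperature cannot be separated from one of the incubator. They do not state that the replicates came from separate plants beyond a leaf taken from each bucket, so the p-values measure the spread between these samples, which may be technical.

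The deposited tables listed 1485 lncRNA transcripts of 1039 loci, each with a value in FPKM, the number of fragments scaled to transcript length and to the mapped fragments of the library, in every library. Of these transcripts, 856 were long intergenic non-coding RNAs (lincRNAs), which lie between protein-coding genes, and 629 were antisense lncRNAs, which are transcribed from the strand opposite another gene. Neither gene symbols, host genes nor positions accompany the identifiers, so transcripts are named here by identifier and locus only. Between 1361 and 1414 transcripts were above 0 in a library, and the median transcript stood at 0.5 to 0.677 FPKM. More transcripts were above 0 in Dongnong422 (1397 ± 11.5, SD, n = 6) than in Kongyu131 (1366 ± 5.14, SD, n = 6), with no overlap between the libraries of the cultivars. These counts include values above 0 but under 0.001 FPKM, 110 to 136 per library in Kongyu131 and 85 to 140 in Dongnong422. In control libraries they were fewer in Dongnong422 (94, 85 and 98) than in Kongyu131 (122, 125 and 136), so they do not account for the higher counts there. The lack of overlap does depend on them. Without them Dongnong422 cold replicate 2, with 140 such values, would not stand above all Kongyu131 libraries. At 1 FPKM or more the cultivars overlapped, with 467 to 574 transcripts in Kongyu131 libraries and 496 to 564 in Dongnong422 libraries. The median lincRNA was above the median antisense lncRNA in 12 of 12 libraries, at 0.528 to 0.743 FPKM against 0.443 to 0.629 FPKM. LNC_000712, a lincRNA of locus XLOC_026914, held 85.7% to 96% of the summed FPKM of the listed lncRNAs of a library. Other RNAs are not in that sum, and FPKM is scaled to length, so this is not a share of the library's fragments. The tables class it as a lincRNA, and whether it is one or another abundant RNA could not be settled, because neither its sequence nor its position was used here. Its level was 393500 ± 41700 FPKM in Kongyu131 control and 409900 ± 183000 in Kongyu131 cold leaves, and 400800 ± 129000 and 650800 ± 450000 in Dongnong422 (SD, n = 3 each). The Dongnong422 cold mean rests on replicate 2, at 1170000 FPKM. Replicates 1 and 3, at 412484 and 369909 FPKM, lay within the range of the Dongnong422 control libraries (274258 to 531710 FPKM). Read numbers were not recoverable from the FPKM values, so the depth of each library is unknown.

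Cultivar was the main source of variation. The first principal component, with 51% of the variance over 1441 lncRNAs, separated Kongyu131 from Dongnong422, and the second, with 11.2%, separated cold from control libraries in both cultivars. Pearson correlations between libraries of a group were 0.851 to 0.897, those between treatments of a cultivar 0.794 to 0.855, and those between cultivars 0.572 to 0.634. Kongyu131 cold replicate 3 stood apart from its group on the third component (−1.24, against 17.01 and 17.77 for the other two). Without it, cold called 86 lncRNAs in Kongyu131, 83 in Dongnong422 and 152 on average, and the cold effects differed for 14, against 105, 70, 182 and 6 with all libraries.

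**Figure D1:**
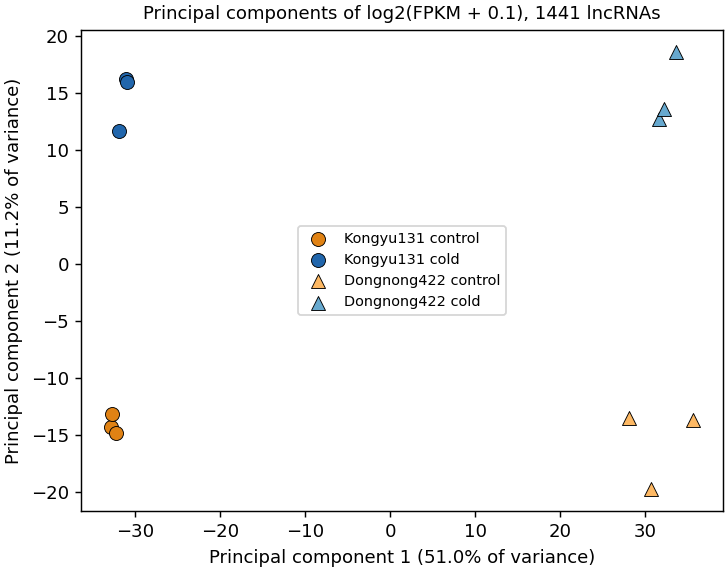
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 0.1) for 1441 lncRNAs, with the share of variance on each axis (51% and 11.2%). Circles are Kongyu131 and triangles Dongnong422, orange shades are control and blue shades cold, and the cultivars lie on opposite sides of the first component while the treatments lie on opposite sides of the second.

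In Kongyu131 leaves, 78 of 1441 lncRNAs fell and 27 rose in the cold on the values as deposited, a balance that moved with the scaling between libraries. The largest fall was in the antisense lncRNA LNC_000185 (locus XLOC_009332), from 86.0 ± 22.8 FPKM in control to 2.39 ± 1.63 FPKM in cold leaves (SD, n = 3 each), 38.7-fold lower on the log2(FPKM + 0.1) scale. The antisense lncRNA LNC_001057 (XLOC_040119) fell from 5.87 ± 1.00 FPKM (SD, n = 3) to 0, 0.383 and 0.837 FPKM in the 3 cold libraries. The largest rise was in the antisense lncRNA LNC_001018 (XLOC_038036), from 0.973 ± 0.901 to 34.1 ± 10.7 FPKM (SD, n = 3 each), 41.9-fold higher. The lincRNA LNC_001213 (XLOC_047408) was listed at 0 in all 3 control libraries and at 2.76, 3.26 and 5.16 FPKM in the cold libraries, and it was the 1 lncRNA at 0 in every control library with at least 1 FPKM in every cold one.

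These calls came from limma with Benjamini-Hochberg adjustment over 1441 lncRNAs. The log2 changes of LNC_000185, LNC_001057 and LNC_001018 were −5.28 (SE 0.668), −4.05 (SE 0.718) and 5.39 (SE 0.656), with adjusted p-values of 0.00489, 0.0158 and 0.00489, and that of LNC_001213 was 0.0457. The log2 change of LNC_001018 was 6.07 and 4.60 without control replicates 1 and 3 of Kongyu131 and 4.21 with a pseudocount of 1 FPKM. That of LNC_001057 was −3.14 and −4.75 without cold replicates 1 and 3, and −2.32 and −5.29 with pseudocounts of 1 and 0.01 FPKM, the latter without a call (adjusted p = 0.0503). The 27 lncRNAs that rose had a median log2 change of 1.95 and the 78 that fell of −1.76, and 26 and 72 of them changed at least 2-fold. With other scalings, 37 rose and 54 fell (median-ratio scaling) and 38 rose and 41 fell (quantile normalization). The total of 105 became 14 without cold replicate 1, 16 without cold replicate 2, 29 and 31 without control replicates 2 and 3, and 51 without cold replicate 1 of Dongnong422. The call of LNC_001213 ended with no variance trend (adjusted p = 0.0589), with a pseudocount of 0.01 FPKM (0.066), and without any of the 6 Kongyu131 libraries and without Dongnong422 control replicate 1 or 3 or cold replicate 1 (adjusted p from 0.0516 to 0.122).

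In Dongnong422 leaves, 46 lncRNAs fell and 24 rose in the cold. LNC_000185 again fell the most, from 32.9 ± 25.4 FPKM in control to 0.330 ± 0.231 FPKM in cold leaves (SD, n = 3 each), 64.2-fold lower. The antisense lncRNA LNC_000052 (XLOC_003075) fell from 2.34 ± 0.886 FPKM (SD, n = 3) to 0, 0 and 0.0978 FPKM in the cold libraries. The lincRNA LNC_000956 (XLOC_035220) rose from 0, 0.166 and 0 FPKM in the control libraries to 2.90, 8.53 and 0.888 FPKM in the cold libraries. The lincRNA LNC_000882 (XLOC_033483) rose from 0.411 ± 0.436 to 6.11 ± 0.771 FPKM (SD, n = 3 each), 17.4-fold higher.

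The limma adjusted p-values were 0.0017 for LNC_000185, 0.00744 for LNC_000052, 0.0176 for LNC_000956 and 0.0196 for LNC_000882. The log2 change of LNC_000185, −6.01, was −6.77 and −5.39 without control replicates 1 and 2 and −4.32 with a pseudocount of 1 FPKM. That of LNC_000882, 4.12, was 4.84 and 3.20 without control replicates 1 and 3, and 2.37 and 5.35 with pseudocounts of 1 and 0.01 FPKM, the latter without a call (adjusted p = 0.0602). The lncRNAs that rose had a median log2 change of 2.1 and those that fell of −1.88, with 23 and 46 of them at least 2-fold. The scaling again moved the balance: 47 rose and 40 fell with median-ratio scaling, and 39 rose and 39 fell with quantile normalization. The total of 70 became 14 without cold replicate 2, 18 without control replicate 3, 33 without control replicate 1, and 35 and 37 without cold replicates 1 and 3. The calls of LNC_000956 and LNC_000882 both ended without control replicate 3 (adjusted p of 0.0609 and 0.0548) or cold replicate 2 (0.0693 each), that of LNC_000956 also without control replicate 1 (0.0501), and that of LNC_000882 without cold replicate 3 (0.0523).

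**Figure D2:**
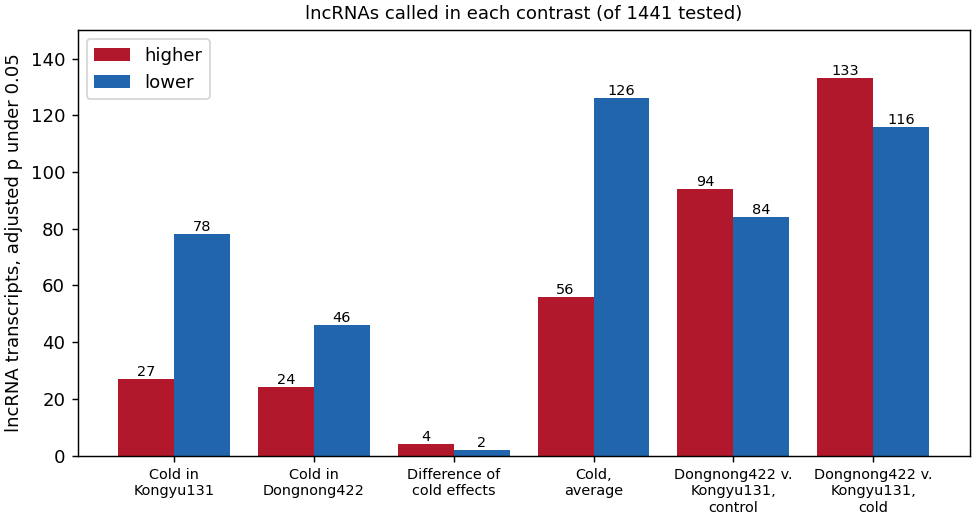
Number of lncRNA transcripts with a limma adjusted p under 0.05 in each of 6 contrasts, of 1441 tested, as bars for transcripts that were higher (red) and lower (blue) in the first-named condition or cultivar. On the values as deposited, the cold contrasts had 27 higher and 78 lower transcripts in Kongyu131 and 24 and 46 in Dongnong422 (47 and 40 with median-ratio scaling), and the cultivar contrast in cold leaves had the most transcripts (249).

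In the joint fit, the cultivars shared more of the falls than independent lists would. Of the lncRNAs that fell, 12 did so in both cultivars, where 2.5 were expected (one-sided Fisher's exact test, p = 2.38e-06). Both lists rest on a common estimate of the spread for each lncRNA, and lncRNAs are not independent. The expected number may therefore be too low and this p-value too small. Of these 12, 8 were lincRNAs and 4 antisense lncRNAs. LNC_000185 fell the furthest among them, followed in Kongyu131 by the lincRNA LNC_000913 (XLOC_033792; log2 change −3.50 in Kongyu131 and −2.75 in Dongnong422), and the 12 log2 changes ran from −1.03 to −5.28 in Kongyu131 and from −1.30 to −6.01 in Dongnong422. A single lncRNA rose in both cultivars, where 0.45 were expected (one-sided Fisher's exact test, p = 0.367). This was the lincRNA LNC_001206, 1 of 2 transcripts of XLOC_047016, named after its values were seen, at 0.0942 ± 0.0932 and 0.478 ± 0.0464 FPKM in control and cold Kongyu131 leaves and 0.329 ± 0.147 and 1.36 ± 0.231 FPKM in Dongnong422 (SD, n = 3 each). Summed over its locus, its log2 rise in Kongyu131 was 0.86 (adjusted p = 0.168). Its Kongyu131 call also ended with a pseudocount of 1 FPKM (adjusted p = 0.0613) or 0.01 FPKM (0.0785) and with the 6 libraries alone (0.116), and its Dongnong422 call with a pseudocount of 0.01 FPKM (0.205) and with the 6 libraries alone (0.0718). The call ended in Kongyu131 without control replicate 1 or 3 or any cold replicate of that cultivar or Dongnong422 cold replicate 1 (adjusted p from 0.0537 to 0.114), and in Dongnong422 without control replicate 2 or 3 or any cold replicate of that cultivar (0.0523 to 0.103).

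Across lncRNAs, which are not independent replicates, the cold effects of the cultivars correlated weakly (Pearson r = 0.226, Spearman rho = 0.222), and none of 99 other assignments of treatment within the cultivars gave a value as large (highest 0.163 and 0.214). Of the 78 lncRNAs that fell in Kongyu131, 61 (78.2%) had a change of the same sign in Dongnong422, as did 21 of the 27 that rose (77.8%), and in Dongnong422 57.1% of all 1441 lncRNAs had a change below 0 and 41.5% above 0. Of those called in Dongnong422, 32 of 46 that fell (69.6%) and 15 of 24 that rose (62.5%) had the same sign in Kongyu131, where 53.8% and 41.2% of all lncRNAs did. These shares were not tested. The contrasts share no library, but the fit gives them a common estimate of the spread for each lncRNA. With each cultivar fitted alone, 1 shared fall was left, where 0.12 were expected. The 13 calls shared in direction became 3 to 8 without any of 9 of the 12 libraries, the lowest without Dongnong422 control replicate 3, and 10 to 16 without Kongyu131 cold replicate 3, Dongnong422 control replicate 2 or Dongnong422 cold replicate 3.

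**Figure D3:**
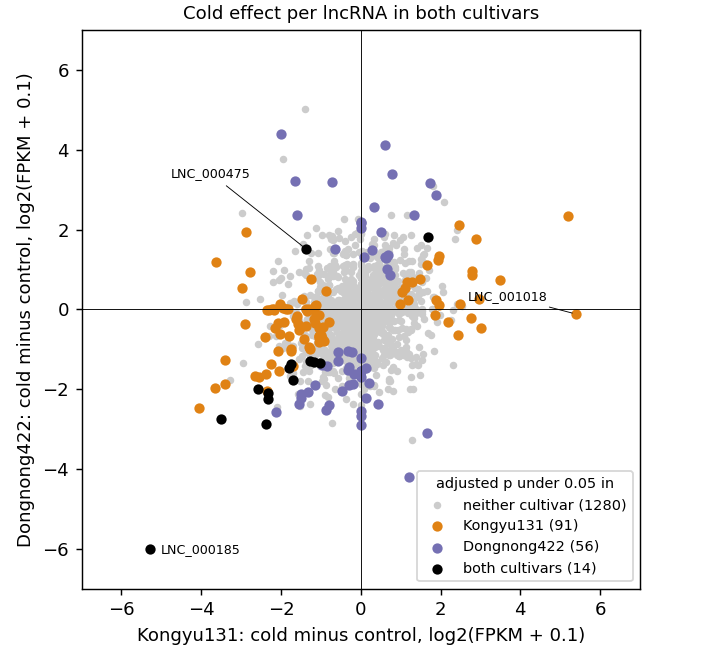
Log2 change in the cold on log2(FPKM + 0.1) in Kongyu131 (horizontal axis) and Dongnong422 (vertical axis), 1 point per lncRNA of 1441, coloured by where limma's adjusted p was under 0.05. Of the black points, called in both cultivars, 12 lie at the lower left with LNC_000185 the furthest out, 1 lies at the upper right, and LNC_000475 lies at the upper left.

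Averaged over the cultivars, 126 lncRNAs fell and 56 rose in the cold. LNC_000185 fell by 5.64 on the log2 scale (SE 0.472, adjusted p = 0.000154) and LNC_000913 fell by 3.12 (SE 0.473, adjusted p = 0.00366). With a pseudocount of 1 FPKM these changes were −4.54 and −1.45, and with 0.01 FPKM that of LNC_000913 was −3.86. LNC_000913 went from 2.26 ± 0.893 to 0.113 ± 0.105 FPKM in Kongyu131 and from 2.80 ± 2.79 to 0.239 ± 0.173 FPKM in Dongnong422 (SD, n = 3 each). The antisense lncRNA LNC_000133 (XLOC_006585) rose on average, with 2.58 ± 0.552 and 7.59 ± 3.83 FPKM in control and cold Kongyu131 leaves and 2.38 ± 0.439 and 7.40 ± 2.78 FPKM in Dongnong422 (SD, n = 3 each; log2 change 1.47, SE 0.286, adjusted p = 0.0097). The lincRNA LNC_000344, 1 of 5 transcripts of XLOC_014676, rose on average, with 0.310 ± 0.330 and 0.872 ± 0.242 FPKM in Kongyu131 and 0.463 ± 0.198 and 1.22 ± 0.225 FPKM in Dongnong422 (SD, n = 3 each; log2 change 1.39, SE 0.347, adjusted p = 0.028, and 0.57 with a pseudocount of 1 FPKM). Neither rise was called within a cultivar. In Kongyu131 and Dongnong422 the limma adjusted p was 0.0605 and 0.0528 for LNC_000133, and 0.0866 and 0.145 for LNC_000344.

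The median log2 change over all 1441 lncRNAs was −0.15, and with median-ratio scaling it was −0.03 with 76 lncRNAs higher and 79 lower. With quantile normalization 78 were higher and 69 lower. The total of 182 became 100 without Dongnong422 cold replicate 2, 103 and 104 without Kongyu131 control and cold replicates 2, and 118 without Dongnong422 control replicate 3. The call of LNC_000344 ended without Kongyu131 control replicate 2 or 3, Kongyu131 cold replicate 3, Dongnong422 control replicate 1 or 3, or Dongnong422 cold replicate 1 or 3 (adjusted p from 0.05 to 0.0669).

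The cold effect itself differed between the cultivars for 6 of the 1441 lncRNAs, each the sole listed transcript of its locus, with 221 at an unadjusted p under 0.05. LNC_001018 rose in Kongyu131 and stood at 1.03 ± 0.725 FPKM in control and 0.814 ± 0.103 FPKM in cold Dongnong422 leaves (SD, n = 3 each), a difference of cold effects of −5.50 (SE 0.927, adjusted p = 0.0275; Dongnong422 minus Kongyu131). LNC_000052 fell in Dongnong422 and stood at 0.834 ± 0.607 and 1.71 ± 0.888 FPKM in control and cold Kongyu131 leaves (difference −5.41, SE 0.914, adjusted p = 0.0275). LNC_000956 rose in Dongnong422 and stood at 2.51 ± 0.847 and 0.776 ± 0.881 FPKM in Kongyu131 (difference 6.40, SE 1.15, adjusted p = 0.0395). The lincRNA LNC_000735 (XLOC_027944) was at 1.38, 0.738 and 1.44 FPKM in the Kongyu131 control libraries and listed at 0 in all 3 cold ones, against 0.596 ± 0.295 and 1.60 ± 0.932 FPKM in Dongnong422 (SD, n = 3 each; adjusted p = 0.0169). The lincRNAs LNC_000475 (XLOC_018030) and LNC_000975 (XLOC_035698) were named after their values were seen. LNC_000475 was the 1 lncRNA called in opposite directions by cold, where 2.2 were expected: it fell from 3.83 ± 1.16 to 1.41 ± 0.362 FPKM in Kongyu131 and rose from 1.76 ± 0.334 to 5.15 ± 0.446 FPKM in Dongnong422 (difference 2.88, SE 0.395, adjusted p = 0.0169). LNC_000975 went from 1.52 ± 0.138 to 0.590 ± 0.0953 FPKM in Kongyu131 and from 1.24 ± 0.210 to 2.16 ± 0.376 FPKM in Dongnong422 (difference 1.99, SE 0.337, adjusted p = 0.0275).

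The 6 calls were all lost without Kongyu131 cold replicate 1 or Dongnong422 control replicate 3 (0 by limma, with 178 and 210 at an unadjusted p under 0.05), and the count was 2 without Dongnong422 cold replicate 2, 3 without Kongyu131 cold replicate 2 or Dongnong422 cold replicate 3, and 14 without Kongyu131 cold replicate 3. It was 12 with quantile normalization, 16 with a pseudocount of 1 FPKM and 3 with 0.01 FPKM. Of the 6 calls, 5 were kept with 1 FPKM, where LNC_000956 was lost (adjusted p = 0.0575), and 3 with 0.01 FPKM, where LNC_000956, LNC_000052 and LNC_001018 were lost (adjusted p = 0.0568 each). With 1 and 0.01 FPKM the difference was 3.03 and 8.98 for LNC_000956, and −2.23 and −8.07 for LNC_000052. Both have 2 of 3 libraries of a Dongnong422 group at 0, so these sizes rest on the pseudocount. With 1 FPKM it was −4.32 for LNC_001018, 2.15 for LNC_000475 and 1.16 for LNC_000975. The difference of LNC_000956 was 7.19 without cold replicate 3 of either cultivar and 5.62 without Dongnong422 cold replicate 2. That of LNC_000052 was −4.59 without Kongyu131 control replicate 3. For LNC_001018 it was −6.19 and −4.72 without Kongyu131 control replicates 1 and 3. Besides Kongyu131 cold replicate 1 and Dongnong422 control replicate 3, the call of LNC_000735 ended without Dongnong422 cold replicate 2 (adjusted p = 0.0536). That of LNC_000052 ended without Kongyu131 cold replicate 2, Dongnong422 control replicate 1 or any Dongnong422 cold replicate (0.0527 to 0.0808). That of LNC_001018 was kept without Kongyu131 control replicate 1 or 3, Kongyu131 cold replicate 3 or Dongnong422 control replicate 1. That of LNC_000956 was kept without Kongyu131 or Dongnong422 cold replicate 3, and that of LNC_000975 without Kongyu131 cold replicate 3 or Dongnong422 control replicate 2. Each of these 3 calls ended without any of the other libraries. For LNC_000475 the fall in Kongyu131 was not called without control replicate 3 (adjusted p = 0.0708), cold replicate 1 (0.0791) or cold replicate 2 (0.0778) of that cultivar or with its 6 libraries alone (0.0893), nor the rise in Dongnong422 without its control replicate 3 (0.0609) or cold replicate 2 (0.0569).

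**Figure D4:**
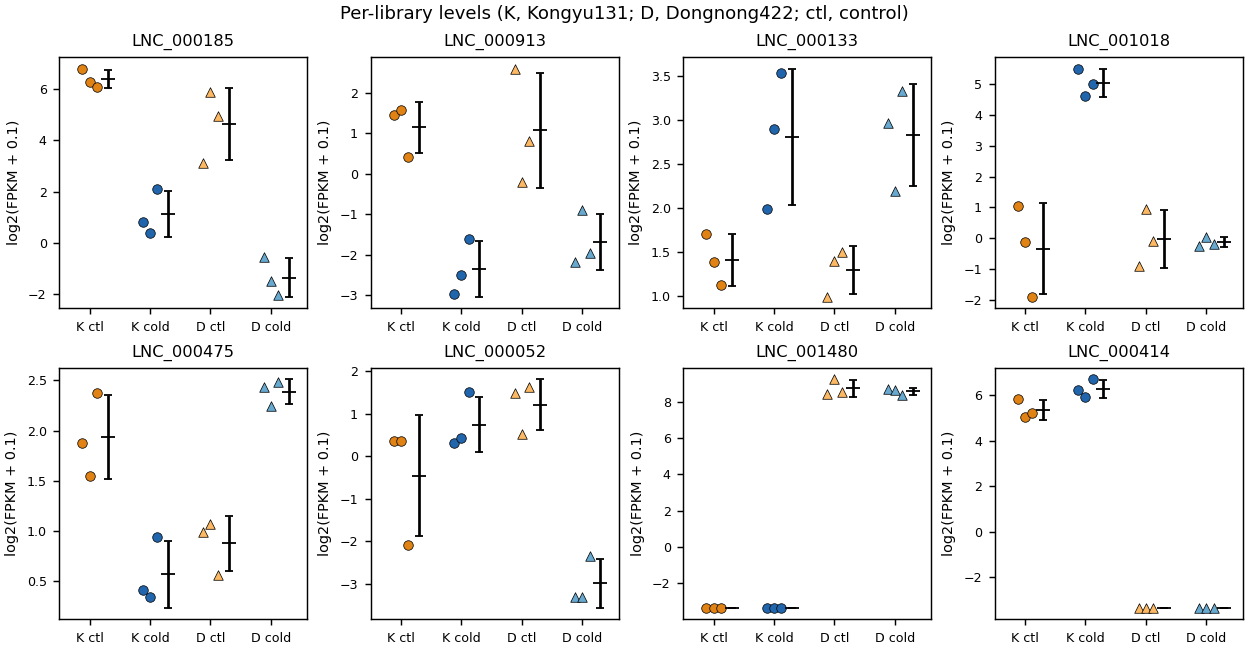
Values of 8 lncRNAs on log2(FPKM + 0.1) in each library, with K for Kongyu131, D for Dongnong422 and ctl for control, and with the mean ± SD of the 3 libraries of a group beside the points. LNC_000185 and LNC_000913 were lower in the cold in both cultivars, LNC_000133 was higher on average, LNC_001018, LNC_000475 and LNC_000052 differed in their cold effect, and LNC_001480 and LNC_000414 were listed at 0, drawn at the floor, in all libraries of a cultivar.

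In control leaves, 94 lncRNAs were higher and 84 lower in Dongnong422 than in Kongyu131, and in cold leaves 133 were higher and 116 lower. The lincRNA LNC_001480 (XLOC_058068) was listed at 0 in all 6 Kongyu131 libraries and stood at 437 ± 145 FPKM in control and 381 ± 49.6 FPKM in cold Dongnong422 leaves (SD, n = 3 each). The lincRNA LNC_000317 (XLOC_013809) was likewise at 0 in Kongyu131, and at 398.5 ± 269 and 275 ± 105 FPKM in Dongnong422. In the other direction, the lincRNAs LNC_000414 (XLOC_016383) and LNC_001030 (XLOC_038619) were at 0 in all 6 Dongnong422 libraries and at 41.8 ± 13.1 and 41.9 ± 12.3 FPKM in control and 79.1 ± 22.1 and 37.8 ± 17.1 FPKM in cold Kongyu131 leaves (SD, n = 3 each).

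The limma adjusted p-values of these 4 lncRNAs ran from 2.82e-11 to 1.99e-08 in control and from 3.25e-11 to 3.05e-08 in cold leaves. Each is listed at 0 in all libraries of a cultivar, and these values without spread lower the common estimate of the spread. Their p-values may therefore be too small. The median log2 difference of the called lncRNAs was 3.88 and −3.08 in control leaves and 2.89 and −2.53 in cold leaves, values that rest in part on the pseudocount because some of these lncRNAs are listed at 0 in a cultivar. Of the calls, 70 were higher and 60 lower in Dongnong422 under both treatments, where 8.7 and 6.8 were expected (one-sided Fisher's exact tests, p = 1.54e-60 and 1.2e-53). The fit gives both contrasts a common estimate of the spread, and transcripts of a locus are not independent. The expected numbers may therefore be too low and these p-values too small. The cultivar differences correlated across lncRNAs between the treatments (Pearson r = 0.764, Spearman rho = 0.347). LNC_000475 and the antisense lncRNA LNC_000681, 1 of 6 transcripts of XLOC_025447 and named after its values were seen, were called in opposite directions, lower in Dongnong422 in control leaves and higher in cold leaves. LNC_000681 stood at 0.404 ± 0.221 and 0.0816 ± 0.140 FPKM in control and cold Kongyu131 leaves and at 0.00011 ± 0.000162 and 0.428 ± 0.126 FPKM in Dongnong422 (SD, n = 3 each). Summed over its locus it was no longer called in either treatment, with a log2 difference of −0.21 (adjusted p = 0.7) in control and of −0.74 (adjusted p = 0.0708) in cold leaves. Its cold call was lost with a pseudocount of 1 FPKM (adjusted p = 0.0761), with quantile normalization (0.0523), with the 6 cold libraries alone (0.101) and without any of 10 libraries (all but Kongyu131 control replicate 3 and Kongyu131 cold replicate 2, adjusted p from 0.055 to 0.164), and its control call without Kongyu131 or Dongnong422 control replicate 1 or 2 (0.0501 to 0.0832).

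Some transcripts were listed in a single cultivar. Over all libraries, 35 transcripts of 32 loci had at least 1 FPKM in all 6 Dongnong422 libraries and were listed at 0 in all 6 Kongyu131 libraries, and 16 transcripts of 15 loci showed the reverse. The 35 comprised 24 lincRNAs and 11 antisense lncRNAs with a median of 6.01 FPKM, and the 16 comprised 14 lincRNAs and 2 antisense lncRNAs with a median of 4.54 FPKM. After LNC_001480 and LNC_000317, the highest was the lincRNA LNC_000721 (XLOC_027198), at 143, 101 and 236 FPKM in the cold and 157, 282 and 423 FPKM in the control libraries of Dongnong422. By treatment, 45 transcripts were at 0 in all 3 Kongyu131 control libraries and at 1 FPKM or more in all 3 Dongnong422 control libraries, with 26 the other way, and the cold libraries gave 40 and 19. Between the treatments of a cultivar the same criterion gave 1 transcript, LNC_001213. No fold is given for these transcripts, because an exact 0 can be a failed estimate.

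LincRNAs differed between the cultivars more often than antisense lncRNAs. In control leaves, 121 of 828 lincRNAs (14.6%) and 57 of 613 antisense lncRNAs (9.3%) were called, and in cold leaves 161 (19.4%) and 88 (14.4%). The odds ratios were 1.67 (two-sided Fisher's exact test, adjusted p = 0.016 over 6 contrasts) and 1.44 (adjusted p = 0.0406). Within 4 equal bins of mean FPKM, an exact stratified test added after the data were seen gave odds ratios of 1.60 (p = 0.00635) and 1.33 (p = 0.0592), which ended the call in cold leaves. With only the highest transcript of each locus, also added after the data were seen, they were 1.76 (two-sided Fisher's exact test, p = 0.0036) and 1.51 (p = 0.0114). Cold called 63 lincRNAs (7.61%) and 42 antisense lncRNAs (6.85%) in Kongyu131 (adjusted p = 0.914) and 39 (4.71%) and 31 (5.06%) in Dongnong422 (adjusted p = 0.966). Neither class moved as a set against the other in any contrast by limma's camera (adjusted p from 0.326 to 0.931 with the preset correlation and adjusted p from 0.777 to 0.957 with an estimated correlation). By fry, which asks whether the members of a class move on balance in a single direction, lincRNAs were lower in the cold on average over the cultivars (adjusted p = 0.0488, median log2 change −0.19). The antisense median there was also below 0 (−0.1, fry adjusted p = 0.182). LincRNAs were higher in Dongnong422 than in Kongyu131 in cold leaves (adjusted p = 0.0488, median log2 difference 0.12). The fry p-values were adjusted over the 6 contrasts within each class, not over both classes together. Unadjusted, those of lincRNAs were 0.0163 for the cold average and 0.0135 for the cultivars in cold leaves. With median-ratio scaling and quantile normalization, both added for fry after the data were seen, the adjusted p was 0.149 and 0.0148 for the cold average and 0.00125 and 0.00199 for the cultivars in cold leaves, where the median was −0.03 with quantile normalization. As deposited, the other 4 contrasts did not pass for lincRNAs (adjusted p from 0.0649 to 0.498), but 3 of them passed under a scaling. Cold in Kongyu131 (lower, adjusted p = 0.00347) and the difference of cold effects (higher, adjusted p = 0.0148) passed with quantile normalization and not with median-ratio scaling (0.0592 and 0.122). The cultivars in control leaves passed with median-ratio scaling (higher in Dongnong422, adjusted p = 0.0185) and not with quantile normalization (0.567). No contrast passed for antisense lncRNAs as deposited (adjusted p from 0.182 to 0.541), and with median-ratio scaling the cultivars in control leaves did (higher in Dongnong422, adjusted p = 0.00389).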

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

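Of the tests below, those on reads assigned to another transcript, on scaling and on assignments of treatment with the average cold effect removed were chosen after the results were seen.

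The difference of the cold effects between cultivars was itself tested, and this singled out 6 of 1441 lncRNAs: LNC_000956 (6.40 on the log2 scale, Dongnong422 minus Kongyu131, and 3.03 and 8.98 with pseudocounts of 1 and 0.01 FPKM), LNC_000052 (−5.41, and −2.23 and −8.07), LNC_000735 (4.82, and 1.76 and 8.15), LNC_001018 (−5.50), LNC_000475 (2.88) and LNC_000975 (1.99), where the sizes of the former 3 rest on the pseudocount because at least 2 libraries of a group are listed at 0. A division of reads with another listed transcript of the locus is argued against, since 6 of 6 are the sole listed transcript of their locus, while a division with an unlisted transcript cannot be told apart for these 6, and scaling is argued against, since 6 of 6 were also called under both median-ratio scaling and quantile normalization. Without any 1 library each difference kept at least 84.9% of its log2 size. This cannot decide on a lone aberrant library, because the calls were selected for a difference that is large against the spread. Leaving out 1 library could then take away only a small part of the size. No call was left without Kongyu131 cold replicate 1 or Dongnong422 control replicate 3. In the test fixed beforehand, 3 of 100 assignments of treatment within the cultivars, the real one included, gave at least 6 calls. The others gave 182 and 7. The 182 came from exchanging cold and control in a single cultivar, which turns the difference into the average cold effect. With the average cold effect removed first, since shuffling treatment breaks it too, only the real one of 100 gave at least 6 calls (highest other 3). The average removed was estimated with the real assignment, which leaves the real difference unchanged and takes signal from the others. The exchange in a single cultivar thus went from 182 calls to 0, so the second test favours the real assignment and cannot decide. Other assignments exceeded the count in the first test, so chance is not excluded. A response that differs between the cultivars may underlie these 6 lncRNAs, beside division with an unlisted transcript, a lone aberrant library and chance. It is a hypothesis found and tested on the same data.

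Cold calls leaned towards lower values, with 69.2% of 182 calls lower on average over the cultivars. With median-ratio scaling 51% were lower and with quantile normalization 46.9%, while 135 and 124 of the 182 calls were kept, and among calls of at least 2-fold the share went from 68.4% to 48% and 44.6%. A scaling difference between libraries cannot be told apart from a true excess of falls by this, because both scalings bring the median change of all lncRNAs from −0.15 to about 0 (−0.03 with median-ratio scaling) and so make the directions more even in part by construction. Whether LNC_000712, which holds most of the listed FPKM, took more fragments in the cold cannot be told apart either: its level and the scale factor of a library had a Spearman correlation of −0.44 over 12 libraries (permutation p = 0.155; Pearson −0.35, p = 0.262), of 0.25 (Pearson) without the 2 libraries farthest from the median, and Pearson correlations of −0.40 and −0.44 within Kongyu131 and Dongnong422. A true excess of falls in the cold stays open, as an untested biological explanation.

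For 51 transcripts, all libraries of a cultivar were listed at 0 and all of the other at 1 FPKM or more. Failed estimates that fall on libraries whatever the cultivar are argued against, since the highest count in any other split of the 12 libraries into 6 and 6 was 1, over 462 splits with the real one, while failures tied to the sequence or level of a locus in a cultivar would give the same and stay open, untested. Assignment of reads to another listed transcript could be tested for 6 transcripts of 4 loci, and is argued against for these, since in 6 of 6 the summed FPKM of the locus was under 0.1 in every library of the lacking cultivar; for the other 45, assignment to an unlisted transcript of the locus cannot be told apart, because their loci list no transcript outside the 51. Sequence differences from the genome used for mapping, or loci missing from a cultivar, may cause the pattern and cannot be told apart from lack of transcription, because 0 genome sequences of either cultivar were used here. The difference between the cultivars' genomes is part of the design and remains open.

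For the average cold effect, 1 of 100 assignments, the real one, gave as many calls (182, highest other 7). This argues against chance in how these libraries vary. It does not cover a chance difference between the plants or places of the groups, because the replicates may be technical. For the contrasts of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05: the real split gave 105 calls for cold in Kongyu131 and 70 in Dongnong422 (highest other 1 each), and 178 and 249 for the cultivars in control and in cold leaves (highest other 1 and 0), with 1 of 10 splits as large each time.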

How the results depend on the processing

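Sums per locus, the overlap from separate fits, the highest transcript per locus, the bins of expression and the scalings for fry were chosen after seeing the data. The 6 counts and the correlation kept a nonzero value of the same sign under the alternatives, except the count of differing cold effects, which reached 0 without either of 2 libraries. A similar count can hold different lncRNAs. With a minimum mean of 1 FPKM, cold called 98 in Kongyu131 and 75 in Dongnong422, of which 58 and 36 were among the calls reported above. With median-ratio scaling these were 81 of 91 and 64 of 87. Counts stayed within 1.5 times the value given in the report except as follows, and where no reason is stated the cause was not tested. With a pseudocount of 0.01 FPKM, cold called 50 lncRNAs in Kongyu131 and 44 in Dongnong422, 3 differed in cold effect, 5 calls were shared and the correlation of cold effects was 0.185, and with 1 FPKM 16 differed and the correlation was 0.265. With a minimum mean of 1 FPKM, which left 559 transcripts, the cultivars differed in 96 in control and 141 in cold leaves and 24 cold calls were shared. Quantile normalization gave 12 differing cold effects. With the 6 libraries compared alone, cold called 23 in Kongyu131 and 20 in Dongnong422, with 1 shared. Of the 23 and 20, 18 and 12 were also called with all libraries. Such fits have fewer degrees of freedom and another estimate of the spread, and the cause was not tested. Sums per locus, over 1036 loci, gave 133 calls for cold in Dongnong422, 17 differing effects and 28 shared calls.

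Libraries with the same replicate number did not deviate together (correlations of −0.11 to 0.08 over 18 pairs, none over 0.1), and 3 of 12 libraries correlated best with their own number, so the numbers do not pair the libraries. With the replicate number as a block the counts were 55 for cold in Kongyu131, 49 in Dongnong422, 119 on average, 2 for differing effects, 166 and 233 for the cultivars, and 8 shared calls, and the calls of LNC_001206 (adjusted p = 0.0601 in Kongyu131 and 0.0507 in Dongnong422), LNC_000681 in cold leaves (0.0641) and the differences of LNC_000956, LNC_000052, LNC_001018 and LNC_000975 (0.0676 each) ended.

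Leaving out each library in turn gave 14 to 113 calls for cold in Kongyu131, 14 to 83 in Dongnong422, 0 to 14 for differing effects, 100 to 192 on average, 157 to 178 and 195 to 258 for the cultivars in control and cold, 3 to 16 shared calls, and correlations of 0.174 to 0.243. A group left with 2 libraries was assumed to vary like the others. For transcripts listed at 0, a minimum of 5 FPKM in place of 1 gave 0 for Kongyu131 control against cold, 19 present in Dongnong422 alone in control and in cold, and 5 and 4 present in Kongyu131 alone. A minimum of 0.1 FPKM gave 66 present in Dongnong422 alone in cold, 45 present in Kongyu131 alone in control and in cold, and 2, 1 and 1 for Kongyu131 cold, Dongnong422 control and Dongnong422 cold against the other treatment.

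All of the 32 values of named lncRNAs kept their direction under each alternative except LNC_000681, whose cultivar difference in cold leaves went to −0.74 summed per locus. All 32 stayed called with median-ratio scaling, and 31 with quantile normalization. LNC_000185, the average cold effects of LNC_000133 and LNC_000913, and the named cultivar differences of LNC_001480, LNC_000317, LNC_000414 and LNC_001030 were called in every setting. The falls of LNC_000913 within each cultivar were not followed through the settings. The calls of LNC_001018 in Kongyu131 (0.0506), LNC_001057 (0.0893), LNC_000956 (0.0871) and LNC_000882 (0.0871), of LNC_000475 in Kongyu131 (0.0893), of LNC_001206 in both cultivars (0.116 and 0.0718) and of LNC_000681 in cold leaves (0.101) ended with the 6 libraries alone, and those of LNC_001057 (0.0503), LNC_000882 (0.0602) and LNC_001213 (0.066) with a pseudocount of 0.01 FPKM, and that of LNC_001213 (0.0589) with no variance trend. By fry, the direction turned, without passing, with median-ratio scaling and quantile normalization for lincRNAs for cold in Dongnong422 (adjusted p = 0.726 and 0.59), for antisense lncRNAs for cold in Kongyu131 (0.216 and 0.116) and on average (0.945 and 0.44), and with quantile normalization for antisense lncRNAs between the cultivars in cold leaves (0.116). The alternative of nearest-gene distance was not run, since the tables pair no gene with a transcript. Depth is unknown.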

Other observations

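Besides LNC_000185 and LNC_000913, the lncRNAs that fell in both cultivars included several of moderate level. The lincRNA LNC_000690 (XLOC_025736) went from 13.3 to 3.81 FPKM in Kongyu131 and from 12.6 to 4.74 FPKM in Dongnong422 (means of 3 libraries), LNC_000804 (XLOC_030014) from 10.2 to 1.89 and from 8.55 to 1.46 FPKM, LNC_001093 (XLOC_041669) from 10.6 to 5.10 and from 10.2 to 4.09 FPKM, and the antisense lncRNA LNC_000105 (XLOC_005810) from 7.57 to 3.10 and from 6.31 to 2.52 FPKM. These 4 were chosen by level after their values were seen.

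A hypothesis was that the cultivars may use different transcripts of the same locus, which predicts more loci with transcripts called in opposite directions between cultivars than when directions are shuffled among the called transcripts. Of 22 loci with 2 or more called transcripts (54 transcripts), 3 held opposite directions, against a median of 13 and a central range of 9 to 18 in 10000 shuffles. As few as 3 came up with a permutation p = 1e-04, the smallest that these shuffles can give, so the prediction failed. Each transcript entered with a single direction, from control leaves or, if not called there, from cold leaves. The shuffles treat transcripts of a locus as independent, although they share the expression of the locus. A low count therefore cannot exclude that some loci use different transcripts. In most of these loci the called transcripts differed between the cultivars in the same direction.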
